A study of Homo sapiens with 9 samples.

How the data were processed

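RNA sequencing of poly(A)-selected RNA from 8 MDA-MB-231 samples was analysed: 2 libraries each of empty vector and RAB11B-AS1 cells, after 24 h at 20% or 1% O2. Per the labels' protocols, cells grew in DMEM with serum, RNA was taken up on RNeasy columns with DNase treatment, and libraries were made with the KAPA mRNA Hyper Prep kit. Whether the counting used strand is not given in the sources used here. Per the submitters' processing notes, the tools were bcl2fastq 2.17, FastQC 0.11.2, TopHat, Picard 1.127, featureCounts, edgeR, Bowtie2 2.2.3 and MACS2 2.0.10, on genome build hg19, without a record of which tool served which assay. A HIF-2alpha ChIP-seq sample of the same series was not analysed here.

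The deposited table holds 18174 genes with a value for each library, and 0 columns were left unmatched to a sample. Its name says FPKM, and the tests were planned for FPKM, but each column of the deposited table sums to 1000000 and the value of 1 read falls with gene length, so the values were treated as TPM, scaled to a common total by the authors. The test is the one planned, on log2(TPM + 1). A common total means that a rise of abundant genes lowers all others slightly. The 10 most abundant genes held 4.38% to 5.36% of the TPM, and the median fold change of all genes lay within 0.04 of 0 (log2) in each comparison under the main and both alternative scalings. Gene names were those of the table, 17579 of which are in the reference gene names. Dates stood in for 24 names, and 21 of these were resolved by position. A total of 56 entries shared position and all values with another entry, and 0 entries were on the mitochondrial genome. Whole reads were recovered from the TPM values by the step that 1 read makes in short genes (615 small RNA genes): 18173 genes (99.99%) came out whole within 0.02 of a read, with a median distance of 1.15e-05, against 0.1% after adding 1% noise. Depth was 18.6 to 25.2 M assigned reads per library, so 3 reads in a gene of 1 kb correspond to 0.335 to 0.468 TPM. This floor of 3 reads per library sets the lower bound of a fold where a group had 0 reads, and covers counting error only. Between 15930 and 16160 genes had a value above 0 per library. Chi-square per gene between the reads of the 2 libraries of a group was 13.9 for empty vector cells at 20% O2, 2.38 at 1% O2, and 1.47 and 1.99 for RAB11B-AS1 cells, so the libraries of each group differed by more than sampling noise and none was counted as a duplicate.

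Before the data were examined, the groups, tests, alternatives, gene lists and the rule for naming genes were fixed. Genes with a TPM of at least 1 in at least 2 libraries (13494) were tested with limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), with 4 group means over all 8 libraries, which share 1 estimate of the spread. Benjamini-Hochberg adjustment at 0.05 was applied within each of 6 comparisons: low oxygen in each line, RAB11B-AS1 at each oxygen level, RAB11B-AS1 averaged over both, and their interaction. Tests were two-sided, and fold changes on this scale understate the change of low genes. Folds stated as such are ratios of mean TPM. A set of 37 gene lists came from textbook knowledge, and the 35 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation (-0.05 to 0.40, median 0.04) and fry were run beside it. Leukocyte markers and mitochondrially encoded genes were too few to test. Genes named were RAB11B-AS1, RAB11B, ANGPTL4, VEGFA, CA9, HIF1A, EPAS1, ARNT, the other tested genes of the locus, genes among the 10 largest changes each way that passed without overlap (5 for the interaction, without that condition), and up to 4 members per list with the smallest p. Not every gene the rule allows is printed, and 1 that passed in the interaction is not reported here. Overlap of calls was set against n1 × n2 / N.

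Alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios and quantile scaling, no variance trend, a replicate block, only the libraries compared, a 2-fold threshold and leaving out each library. Voom on the recovered reads, removal of a length trend and genes of at least 300 bp only were added after seeing the data. The test was checked on simulated data with 200 of 13345 genes changed, 100 by 2-fold and 100 by 1.5-fold. For low oxygen in empty vector cells, 86% and 72% of them were recovered, with 15 of 173 calls among unchanged genes, and for the interaction 78% and 61%, with 12 of 151. RAB11B-AS1 at 20% O2, which carried no simulated change, gave 3 calls. All simulated genes and groups had 1 dispersion and no length shift, unlike the real libraries, and few genes were changed. The simulation therefore does not test the shared spread or how stable the real counts are. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made summaries and figures.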

Results

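Messenger RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, that carried an empty vector or overexpressed RAB11B-AS1. RAB11B-AS1 is a long noncoding RNA whose gene lies antisense to RAB11B on chromosome 19. Each line was kept at 20% or at 1% O2 for 24 h, which gave 4 groups of 2 libraries. The comparisons ask what low oxygen does in each line and how RAB11B-AS1 cells differ from empty vector cells at each oxygen level. They also ask whether the response to low oxygen differs between the lines. An effect of the RNA cannot be told apart from another lasting difference between the lines. Where a gene is said to rise or fall with RAB11B-AS1, this describes a difference between the lines. Expression was available as TPM (transcripts scaled to a total of 1000000) for 18174 genes, from which the reads assigned to genes were recovered. Empty vector cells had 25.2 and 18.6 M reads at 20% O2 and 24.4 and 21.5 M reads at 1% O2. RAB11B-AS1 cells had 24.4 and 23.0 M reads at 20% O2 and 23.5 and 23.8 M reads at 1% O2. Across genes, Pearson's correlation of log2(TPM + 1) was 0.991 to 0.995 between the libraries of a group and 0.962 to 0.984 between groups, where genes are not independent replicates. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. In empty vector cells at 20% O2, replicate 2 read higher than replicate 1 for long transcripts, by a median of 0.24 on the log2 scale for the 199 genes over 12 kb and of 0.16 for the 1095 genes of 7 to 12 kb. The counts of each comparison that uses this group are therefore also given without replicate 2. A similar total there does not mean the same genes, since in these fits some calls were lost and others gained. Which of the 2 libraries is the shifted one was not tested. Pairwise differences given as passing had no overlap, in that both libraries of one group lay above both libraries of the other.

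RAB11B-AS1 (chromosome 19, 8439260 to 8455575, minus strand, hg19) stood at 3.95 ± 0.024 TPM in empty vector cells at 20% O2 and at 45.9 ± 3.0 TPM in RAB11B-AS1 cells (SD, n = 2 libraries). This 11.6-fold difference passed (limma log2 fold change 3.24 ± 0.09 SE, adjusted p = 1.8e-06). At 1% O2 it stood at 6.82 ± 0.24 and 62.6 ± 7.7 TPM, 9.18-fold apart (3.02 ± 0.09, adjusted p = 2.3e-06). Low oxygen itself raised RAB11B-AS1 1.73-fold in empty vector cells (0.66 ± 0.09, adjusted p = 0.0018) and 1.36-fold in RAB11B-AS1 cells (0.44 ± 0.09, adjusted p = 0.0077). The latter call was lost without replicate 2 at 20% O2 (0.37) or replicate 1 at 1% O2 (0.31) of that line. RAB11B (8455205 to 8469317, plus strand), which encodes a small GTPase of recycling endosomes, overlaps RAB11B-AS1 at one end. Whether the counting used strand is not stated, and without it reads in the overlap cannot be told apart. RAB11B rose at 1% O2 from 175 ± 29.4 to 230.4 ± 7.96 TPM in empty vector cells (adjusted p = 0.013) and from 183 ± 1.48 to 236 ± 2.97 TPM in RAB11B-AS1 cells (adjusted p = 0.018). It differed between the lines by 0.08 ± 0.09 at 20% O2 (adjusted p = 0.56) and by 0.04 ± 0.09 at 1% O2 (adjusted p = 0.80). ANGPTL4 (8429011 to 8439257, plus strand), a secreted inhibitor of lipoprotein lipase, ends just beside RAB11B-AS1. With RAB11B-AS1 it fell at 20% O2 from 12.8 ± 0.39 to 8.56 ± 0.53 TPM (-0.53 ± 0.07, adjusted p = 8.3e-04), whereas at 1% O2 the difference of -0.14 ± 0.07 did not pass (adjusted p = 0.15).

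**Figure D1:**
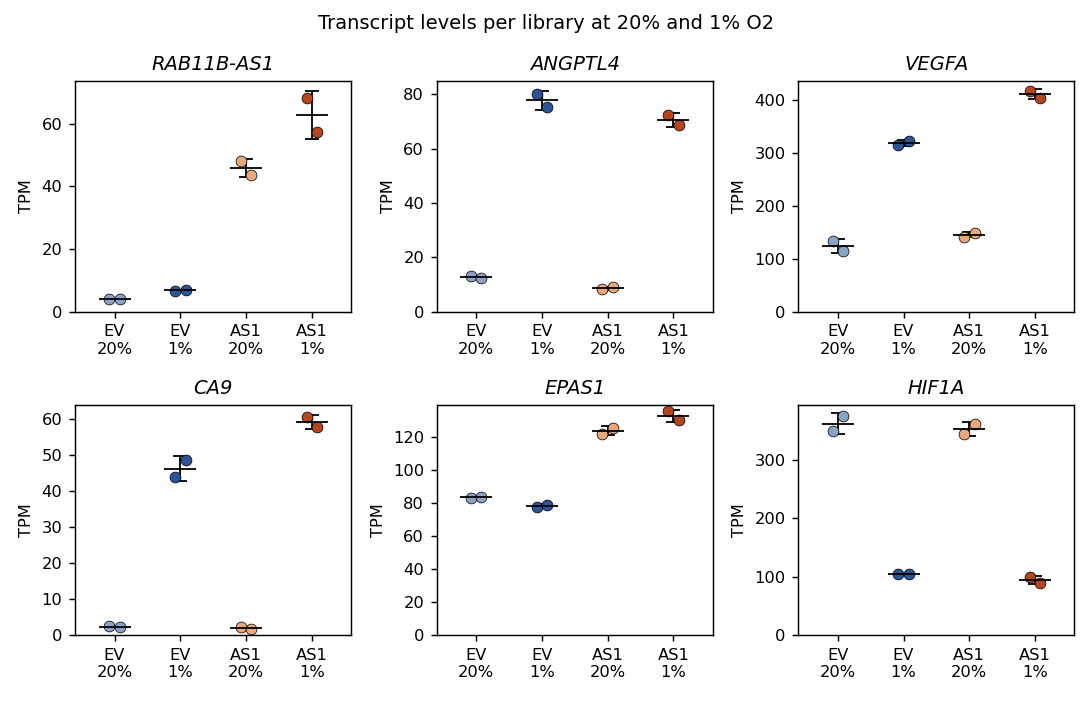
TPM (y axis) of RAB11B-AS1, ANGPTL4, VEGFA, CA9, EPAS1 and HIF1A in the 4 groups of 2 libraries (x axis), with a point per library, a horizontal bar at the mean and error bars of 1 SD. RAB11B-AS1 has means of 3.95 and 6.82 TPM in empty vector cells and of 45.9 and 62.6 TPM in RAB11B-AS1 cells, and HIF1A is lower at 1% O2 in both lines.

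Of the 12 tested genes of the RAB11B-AS1 locus, which include RAB11B and ANGPTL4, 0 rose and 3 fell with RAB11B-AS1 at 20% O2, and 1 rose and 4 fell at 1% O2, with equal counts adjusted over the list alone. Camera called the list in none of the 6 comparisons (adjusted p = 0.55 and 0.28 in these). MYO1F, an unconventional myosin, fell at both levels (limma, -1.32 ± 0.13, adjusted p = 2.4e-04, and -1.03 ± 0.13, adjusted p = 6.4e-04), as did CERS4, a ceramide synthase (-0.85 ± 0.15 and -0.47 ± 0.15). CD320 (-0.26), ELAVL1 (-0.17) and TIMM44 (0.29) passed at 1% O2, and HNRNPM, MARCH2, ZNF414, NDUFA7 and RPS28 passed at neither. Low oxygen raised 2, RAB11B and ANGPTL4, and lowered 3 of the 12 in empty vector cells, where HNRNPM, a splicing factor (-0.38), ELAVL1 (-0.20) and TIMM44 (-0.16) fell. In RAB11B-AS1 cells it raised the same 2 and lowered 2, where HNRNPM (-0.45) and ELAVL1 (-0.32) fell.

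Low oxygen in empty vector cells raised the genes of the hypoxia response. CA9, the cell-surface carbonic anhydrase that regulates pH, rose 18.9-fold from 2.45 ± 0.20 to 46.3 ± 3.4 TPM (SD, n = 2; limma log2 fold change 3.78 ± 0.11 SE, adjusted p = 9.5e-07). The stress gene NDRG1 rose 11.7-fold from 164 ± 14.5 to 1915 ± 90.3 TPM (3.54 ± 0.07). DDIT4, an inhibitor of mTORC1 signalling, rose 8.31-fold (3.04 ± 0.08), IL8, a neutrophil chemokine, 6.61-fold (2.67 ± 0.09), and ANGPTL4 6.07-fold to 77.8 ± 3.5 TPM (2.51 ± 0.07, adjusted p = 6.9e-07). VEGFA (chromosome 6, 43737946 to 43754223), the main angiogenic growth factor, rose 2.56-fold from 125 ± 12.9 to 318 ± 5.83 TPM (1.35 ± 0.07, adjusted p = 1.2e-05). HIF1A, which encodes the oxygen-regulated HIF-1alpha subunit, fell from 362 ± 17.5 to 105 ± 0.68 TPM (-1.78 ± 0.06, adjusted p = 1.1e-06). EPAS1, which encodes HIF-2alpha, differed by -0.09 ± 0.04 (adjusted p = 0.11) and ARNT, their common partner, by 0.03 ± 0.05 (adjusted p = 0.70). Of 13494 genes tested, 2113 rose and 2541 fell at an adjusted p of at most 0.05, 183 and 56 of them by 2-fold or more. The total of 4654 was 4671 without replicate 2 of this line at 20% O2, and 2902 or 2552 without its replicate 1 or 2 at 1% O2. It was 2413 when only these 4 libraries were fitted.

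Most core hypoxia genes rose in empty vector cells. Of 49, 47 rose and 0 fell (48 and 0 adjusted over the list alone), among them BNIP3, a mitophagy receptor (2.05), PGK1 (1.44) and P4HA1, a collagen prolyl hydroxylase (1.80). The core hypoxia list passed camera (adjusted p = 5.2e-42, and adjusted p = 0.012 with an estimated correlation). Of 22 glycolysis genes, 20 rose and 1 fell, including LDHA, which rose from 2056 ± 16.7 to 4481 ± 178 TPM, and the glucose transporter SLC2A3 (1.51). The glycolysis list passed camera (adjusted p = 2.6e-18, but adjusted p = 0.059 with an estimated correlation). Of 29 angiogenic factors, 22 rose and 2 fell (25 and 2 adjusted over the list alone), with STC1 at 1.72. The angiogenic list passed camera (adjusted p = 7.4e-11, and adjusted p = 0.027 with an estimated correlation). Of 25 amino acid starvation genes of the ATF4 pathway, 23 rose and 0 fell, such as asparagine synthetase ASNS (1.57) and CHAC1 (1.95). The starvation list passed camera (adjusted p = 2.7e-18, but adjusted p = 0.099 with an estimated correlation). Of 20 unfolded protein response genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone), with HERPUD1 at 1.51. The unfolded protein list passed camera (adjusted p = 9.5e-09, but adjusted p = 0.12 with an estimated correlation).

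Genes of cell division, respiration and ribosome production fell at 1% O2 in empty vector cells. Of 32 G2/M genes, 0 rose and 25 fell (0 and 27 adjusted over the list alone), such as CCNB1 (-0.44) and AURKA (-0.39). The G2/M list passed camera (adjusted p = 8.3e-09, but adjusted p = 0.099 with an estimated correlation). Of 44 nuclear genes of oxidative phosphorylation, 0 rose and 25 fell (0 and 27 adjusted over the list alone), such as ATP5A1 (-0.31) and SDHB (-0.32). The respiration list passed camera (adjusted p = 3.3e-07, and adjusted p = 0.027 with an estimated correlation). Of 23 ribosome biogenesis genes, 1 rose and 19 fell (1 and 21 adjusted over the list alone), with RRS1 at -0.70. The biogenesis list passed camera (adjusted p = 1.9e-08, and adjusted p = 0.027 with an estimated correlation). The 10 genes with the most negative fold changes were all shorter than 300 bp. Among them SNORD45B, a small nucleolar RNA gene, fell from 73.5 ± 1.6 to 10.4 ± 1.6 TPM (limma, -2.71 ± 0.15, adjusted p = 2.3e-05).

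Low oxygen in RAB11B-AS1 cells also raised hypoxia genes. CA9 rose 29.1-fold from 2.03 ± 0.41 to 59.2 ± 1.9 TPM (SD, n = 2; limma log2 fold change 4.32 ± 0.11 SE, adjusted p = 4.1e-07) and NDRG1 16.3-fold to 2132 ± 94.1 TPM (4.01 ± 0.07). ANGPTL4 rose 8.26-fold to 70.7 ± 2.6 TPM (2.91 ± 0.07, adjusted p = 3.2e-07) and VEGFA 2.82-fold from 146 ± 5.31 to 410.4 ± 9.4 TPM (1.49 ± 0.07, adjusted p = 5.1e-06). DUSP1, an immediate early phosphatase of MAP kinases, rose 7.80-fold from 30.7 ± 3.4 to 239.7 ± 18.7 TPM (2.92 ± 0.09). SLAMF9, with 3 reads at 20% O2, stood at 0.154 TPM there and at 6.07 TPM at 1% O2. HIF1A fell from 353 ± 11.5 to 95.0 ± 6.6 TPM (-1.88 ± 0.06, adjusted p = 8.7e-07). EPAS1 differed by 0.10 ± 0.04 (adjusted p = 0.085) and ARNT by -0.04 ± 0.05 (adjusted p = 0.55). In total 2443 genes rose and 2947 fell, 236 and 90 of them by 2-fold or more. The 5390 calls became 3161 or 3332 without replicate 1 or 2 of this line at 20% O2, and 3391 or 3445 without its replicate 1 or 2 at 1% O2. They became 6616 when only the libraries of this line were fitted.

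Core hypoxia genes in RAB11B-AS1 cells went 44 up and 0 down of 49, with equal counts adjusted over the list alone (camera, adjusted p = 4.0e-32, and adjusted p = 0.020 with an estimated correlation). NF-kB and inflammatory genes went 22 up and 1 down of 25 (camera, adjusted p = 1.6e-13, and adjusted p = 0.031 with an estimated correlation). Among them were PTGS2, the inducible prostaglandin synthase (2.44), and BIRC3, an inhibitor of apoptosis (1.55). In empty vector cells 14 of these genes rose and 1 fell (16 and 2 adjusted over the list alone). Nuclear oxidative phosphorylation genes went 0 up and 30 down of 44 (camera, adjusted p = 5.3e-09, and adjusted p = 0.031 with an estimated correlation), with ATP5B at -0.32. Tricarboxylic acid cycle genes went 1 up and 19 down of 22 (camera, adjusted p = 1.8e-06, and adjusted p = 0.031 with an estimated correlation). Cholesterol synthesis genes went 2 up and 13 down of 23 (2 and 14 adjusted over the list alone), among them HMGCS1 (-0.55) and FDFT1 (-0.41). This list passed camera (adjusted p = 0.0027, but adjusted p = 0.13 with an estimated correlation). The hypoxia comparisons in the 2 lines share no library. Across the 13494 genes, Pearson's correlation of their fold changes was 0.713 and Spearman's 0.715. Both lines raised 1529 of the genes, against 383 for independent lists, and lowered 1876, against 555, while 23 were called in opposite directions.

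RAB11B-AS1 cells at 20% O2 differed from empty vector cells in 4402 genes. SLC12A7, a potassium-chloride cotransporter on chromosome 5 (1050489 to 1112172), rose 15.7-fold from 2.77 ± 0.18 to 43.5 ± 0.18 TPM (SD, n = 2; limma log2 fold change 3.56 ± 0.08 SE, adjusted p = 6.5e-07). It lies in a stretch of genes that are jointly higher in this line. KIAA1199, a hyaluronan-binding protein, rose 10.4-fold to 39.3 ± 0.43 TPM (3.08 ± 0.09), and CD33, a sialic acid-binding receptor, 21.8-fold to 9.82 ± 0.72 TPM (2.90 ± 0.12). PIK3R6, a regulatory subunit of PI3-kinase gamma, stood at 0.0184 TPM in empty vector and 5.32 TPM in RAB11B-AS1 cells. LOC100505817 fell from 92.1 ± 8.8 to 0.506 ± 0.12 TPM (-5.95 ± 0.12, adjusted p = 4.1e-07) and APCDD1L from 23.9 ± 0.30 to 0.483 ± 0.10 TPM (-4.07 ± 0.11). KRBOX1, at 36.4 ± 1.2 TPM in empty vector cells, had 0 reads and was at least 70.0-fold lower (floor of 3 reads per library, counting error only). C5orf46 was at least 21.8-fold lower by the same floor. EPAS1 rose from 83.5 ± 0.32 to 124 ± 2.5 TPM (0.56 ± 0.04, adjusted p = 7.0e-05). HIF1A differed by -0.04 ± 0.06 (adjusted p = 0.66), ARNT by -0.03 ± 0.05 (adjusted p = 0.64) and CA9 by -0.19 ± 0.11 (adjusted p = 0.22). VEGFA passed at 0.23 ± 0.07 (adjusted p = 0.034), but 7 of the 8 fits without 1 library lost the call (0.12 to 0.33), all except that without replicate 1 of empty vector cells at 20% O2. In all, 2115 genes rose and 2287 fell, 197 and 196 of them by 2-fold or more. The 4402 calls became 4356 without replicate 2 of empty vector cells at 20% O2, and 2485 or 2374 without replicate 1 or 2 of RAB11B-AS1 cells at 20% O2. They became 2734 when only the 4 libraries compared were fitted.

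Among the fixed lists at 20% O2, endoplasmic reticulum stress and interferon genes were higher in RAB11B-AS1 cells. Of 20 unfolded protein response genes, 18 rose and 1 fell (camera, adjusted p = 4.0e-08, but adjusted p = 0.45 with an estimated correlation). They include the chaperone HSPA5, from 633 ± 3.3 to 1126 ± 109 TPM (0.83 ± 0.07), and PDIA4, a disulfide isomerase that lies in a jointly higher stretch of chromosome 7 (1.00 ± 0.05). Of 35 interferon response genes, 21 rose and 4 fell (23 and 5 adjusted over the list alone), such as IFIT2 (1.21), IFIT3 (0.99) and the oligoadenylate synthetase OAS3 (1.00). The interferon list passed camera (adjusted p = 3.9e-06, but adjusted p = 0.45 with an estimated correlation). NF-kB genes went 12 up and 3 down of 25 (camera, adjusted p = 0.0020, but adjusted p = 0.45 with an estimated correlation), with the cytokine IL6 at 1.27 and BIRC3 at 1.19. S-phase genes went 15 up and 1 down of 36 (16 and 2 adjusted over the list alone), with the licensing factor CDC6 at 0.45. The S-phase list passed camera (adjusted p = 0.0028, but adjusted p = 0.45 with an estimated correlation). Histone genes went 0 up and 6 down of 14 (0 and 7 adjusted over the list alone), with HIST1H2BK at -1.48. The histone list passed camera (adjusted p = 0.0036, but adjusted p = 0.48 with an estimated correlation).

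Hypoxia and angiogenesis genes went both ways at 20% O2. Core hypoxia genes went 8 up and 17 down of 49 (10 and 18 adjusted over the list alone) and angiogenic factors 6 up and 14 down of 29. Camera called neither (adjusted p = 0.50 and 0.11). Of the angiogenic factors, TGFA (1.17, in a jointly higher stretch of chromosome 2) and EREG (1.33), both EGF receptor ligands, rose and STC1 (-1.17) fell. Of 6 fibroblast and endothelial markers, 1 rose and 3 fell (camera, adjusted p = 0.19). THY1, at 2.38 ± 0.13 TPM in empty vector cells, was at least 15.9-fold lower. Of 11 epithelial markers, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with the tight junction gene CLDN4 at 1.05. The epithelial list passed camera (adjusted p = 0.018, but adjusted p = 0.48 with an estimated correlation). Camera called 10 of 35 lists, and with an estimated correlation 0 (3 at an unadjusted p under 0.05). Fry, which tests whether a list's genes move one way, called 25.

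At 1% O2, 21 of 25 NF-kB and inflammatory genes were higher in RAB11B-AS1 than in empty vector cells and 1 was lower. Their list passed camera, but not with an estimated correlation (adjusted p = 0.14). CSF2, which encodes the growth factor GM-CSF, rose 7.04-fold from 4.87 ± 0.98 to 34.3 ± 4.1 TPM (SD, n = 2; limma log2 fold change 2.59 ± 0.14 SE, adjusted p = 2.0e-05). TRAF1, a signalling adaptor, rose 6.24-fold from 9.43 ± 0.58 to 58.8 ± 2.8 TPM (2.52 ± 0.08), and the stress cytokine GDF15 5.99-fold (2.53 ± 0.13). SLC12A7 rose 12.1-fold (3.16 ± 0.08, in the shifted stretch) and KIAA1199 10.3-fold to 59.5 ± 5.4 TPM (3.15 ± 0.09). LOC100505817 fell from 112 ± 9.5 to 0.674 ± 0.22 TPM (-6.08 ± 0.12, adjusted p = 3.5e-07), and KRBOX1 was at least 47.8-fold lower. C5orf46 stood at 43.1 and 0.113 TPM. ALDOC, a glycolytic aldolase, fell from 12.5 ± 0.38 to 0.925 ± 0.27 TPM (-2.81 ± 0.16). VEGFA rose from 318 to 410.4 TPM (0.36 ± 0.07, adjusted p = 0.0040) and EPAS1 from 78.2 ± 1.0 to 133 ± 3.7 TPM (0.76 ± 0.04, adjusted p = 1.9e-05). HIF1A (-0.14 ± 0.06, adjusted p = 0.085) and ARNT (-0.11 ± 0.05, adjusted p = 0.15) did not pass. CA9 passed at 0.35 ± 0.11 (adjusted p = 0.037), but not with a pseudocount of 0.1, without the filter, or without any 1 of the 4 libraries at 1% O2 (0.28 to 0.42). In all, 2392 genes rose and 2538 fell, 204 and 197 of them by 2-fold or more. The 4930 calls became 3140 or 3223 without replicate 1 or 2 of empty vector cells at 1% O2, and 3019 or 3113 without replicate 1 or 2 of RAB11B-AS1 cells at 1% O2. With only the 4 libraries at 1% O2 fitted, there were 5649.

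NF-kB and inflammatory genes at 1% O2 went 21 up and 1 down of 25 with RAB11B-AS1 (21 and 2 adjusted over the list alone). The NF-kB list passed camera (adjusted p = 8.1e-11, but adjusted p = 0.14 with an estimated correlation). BIRC3 rose from 16.3 ± 0.45 to 66.5 ± 0.73 TPM (1.96 ± 0.07) and IL6 by 1.57 ± 0.08. Unfolded protein response genes went 19 up and 1 down of 20 (camera, adjusted p = 8.1e-11, but adjusted p = 0.22 with an estimated correlation). PDIA4, in its shifted stretch, rose from 297 to 608 TPM (1.03 ± 0.05) and the co-chaperone DNAJB9 by 1.06. Interferon response genes went 22 up and 3 down of 35 (23 and 4 adjusted over the list alone). Their list passed camera (adjusted p = 1.9e-05, but adjusted p = 0.22 with an estimated correlation). Immediate early genes went 13 up and 2 down of 19 (14 and 2 adjusted over the list alone), with the transcription factor EGR1 at 1.45 and MYC at 0.56. The immediate early list passed camera (adjusted p = 4.2e-04, but adjusted p = 0.44 with an estimated correlation). Cholesterol synthesis genes went 1 up and 14 down of 23 (1 and 15 adjusted over the list alone). The cholesterol list passed camera (adjusted p = 5.1e-04, but adjusted p = 0.22 with an estimated correlation). IDI1 (-1.10) and MSMO1 (-0.91) lie in jointly lower stretches of chromosomes 10 and 4, and MVD (-0.58) does not.

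Further lists that camera called lower in RAB11B-AS1 cells at 1% O2 included TGF-beta targets and anti-angiogenic factors. TGF-beta targets went 1 up and 10 down of 15 (camera, adjusted p = 5.9e-04, but adjusted p = 0.26 with an estimated correlation), with PMEPA1 at -1.36 and the matrix protein TGFBI at -2.17. Anti-angiogenic factors went 0 up and 3 down of 9 (camera, adjusted p = 0.035, but adjusted p = 0.26 with an estimated correlation). Among them were the thrombospondins THBS1, from 462 ± 8.2 to 242 ± 6.8 TPM (-0.93 ± 0.04), and THBS2 (-1.83 ± 0.15). Angiogenic factors went 9 up and 11 down of 29 (9 and 13 adjusted over the list alone). Their mean log2 fold change was 0.03 and their median -0.08, camera and fry gave opposite directions, and camera did not call the list (adjusted p = 0.56). Collagen and matrix crosslinking genes went 4 up and 9 down of 21 (5 and 10 adjusted over the list alone; camera, adjusted p = 0.15). Core hypoxia genes went 8 up and 16 down of 49 (8 and 17 adjusted over the list alone; camera, adjusted p = 0.078). Fibroblast and endothelial markers went 1 up and 3 down of 6 (camera, adjusted p = 0.25). Camera called 13 of 35 lists, and with an estimated correlation 0 (7 at an unadjusted p under 0.05), while fry called 28.

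Averaged over both oxygen levels, RAB11B-AS1 itself was higher by 3.13 ± 0.07 (limma log2 fold change ± SE, adjusted p = 1.2e-07). Higher too were SLC12A7 (3.36 ± 0.06), KIAA1199 (3.11 ± 0.06), PCBP3, an RNA-binding protein (2.90 ± 0.08), GDF15 (2.27 ± 0.09) and the collagen gene COL6A2 (1.76 ± 0.04). Lower were LOC100505817 (-6.02 ± 0.09), EMC10, a subunit of an endoplasmic reticulum membrane complex (-2.70 ± 0.07), and TGFBI (-2.25 ± 0.06). EPAS1 was higher by 0.66 ± 0.03 (adjusted p = 2.8e-06), VEGFA by 0.30 ± 0.05 (adjusted p = 0.0013) and EGLN3, a HIF prolyl hydroxylase, by 0.94 ± 0.04. ANGPTL4 was lower (-0.33 ± 0.05, adjusted p = 7.5e-04). RAB11B (0.06 ± 0.07, adjusted p = 0.52), CA9 (0.08 ± 0.08, adjusted p = 0.43), HIF1A (-0.09 ± 0.04, adjusted p = 0.10) and ARNT (-0.07 ± 0.04, adjusted p = 0.15) did not pass. In all, 3077 genes were higher and 3270 lower, and the total of 6347 was 6969 without replicate 2 of empty vector cells at 20% O2. It was 5061 to 5353 without any 1 library of the other 3 groups. Of the lists, NF-kB genes went 19 up and 2 down of 25 (camera, adjusted p = 3.9e-07, but adjusted p = 0.27 with an estimated correlation). Homologous recombination genes went 10 up and 1 down of 17 (camera, adjusted p = 0.0037, but adjusted p = 0.51 with an estimated correlation). Nuclear oxidative phosphorylation genes went 1 up and 22 down of 44 (2 and 24 adjusted over the list alone). The averaged respiration list passed camera (adjusted p = 0.0011, but adjusted p = 0.26 with an estimated correlation). The RAB11B-AS1 comparisons at 20% and 1% O2 share no library. Across 13494 genes Pearson's correlation of their fold changes was 0.756 and Spearman's 0.702. At both levels 1491 genes were up, against 375 for independent lists, and 1669 down, against 430.1, while 24 were called in opposite directions.

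Neighbouring genes often differed together between the lines. Around each tested gene the median log2 fold change of the 20 nearest genes was taken, a measure chosen after seeing the data. In 15 stretches of at least 20 genes this median was 0.25 or more in size, 7 higher and 8 lower in RAB11B-AS1 cells, with 975 genes. The largest was on chromosome 4 (84184977 to 190884359), where 201 of 251 genes passed as lower and 4 as higher on average, and the median was -0.41 at 20% O2 and -0.36 at 1% O2. It holds the histone gene H2AFZ. Stretches of 65, 55, 47 and 22 genes elsewhere on chromosome 4 were also lower, with medians of -0.31 to -0.42 at 20% O2. Higher stretches of 27 and 26 genes lay side by side on chromosome X. The 15 stretches may therefore not be separate events. On chromosome 10 (180405 to 35501886) 100 of 116 genes passed as lower and 2 as higher, with medians of -0.58 and -0.54, among them the integrin gene ITGB1 (-0.76 ± 0.03 on average). On chromosome 2 (68269332 to 85788657) 76 of 89 genes passed as higher and 3 as lower, with medians of 0.43 and 0.40, among them TGFA and the mitochondrial folate enzyme MTHFD2. On chromosome 5 (204875 to 27496508) 38 of 48 passed as higher and 3 as lower, with medians of 0.33 and 0.42, among them SLC12A7. A second stretch of chromosome 5 (140090861 to 141016423), where 34 of 37 genes passed as lower and 1 as higher, had medians of -0.36 at 20% O2 and -0.77 at 1% O2, a difference that was not tested. Its medians for low oxygen were 0.13 in empty vector and -0.27 in RAB11B-AS1 cells. It spans only 0.926 Mb, from VTRNA1-1 to HDAC3, and whether its 37 entries overlap or share reads was not examined. They may therefore not count as independent genes. Counted without the minimum of 20 genes per stretch, genes with such a median around them were 9.09% of the tested genes. In the hypoxia comparisons of empty vector and RAB11B-AS1 cells they were 0.415% and 1.14%.

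**Figure D2:**
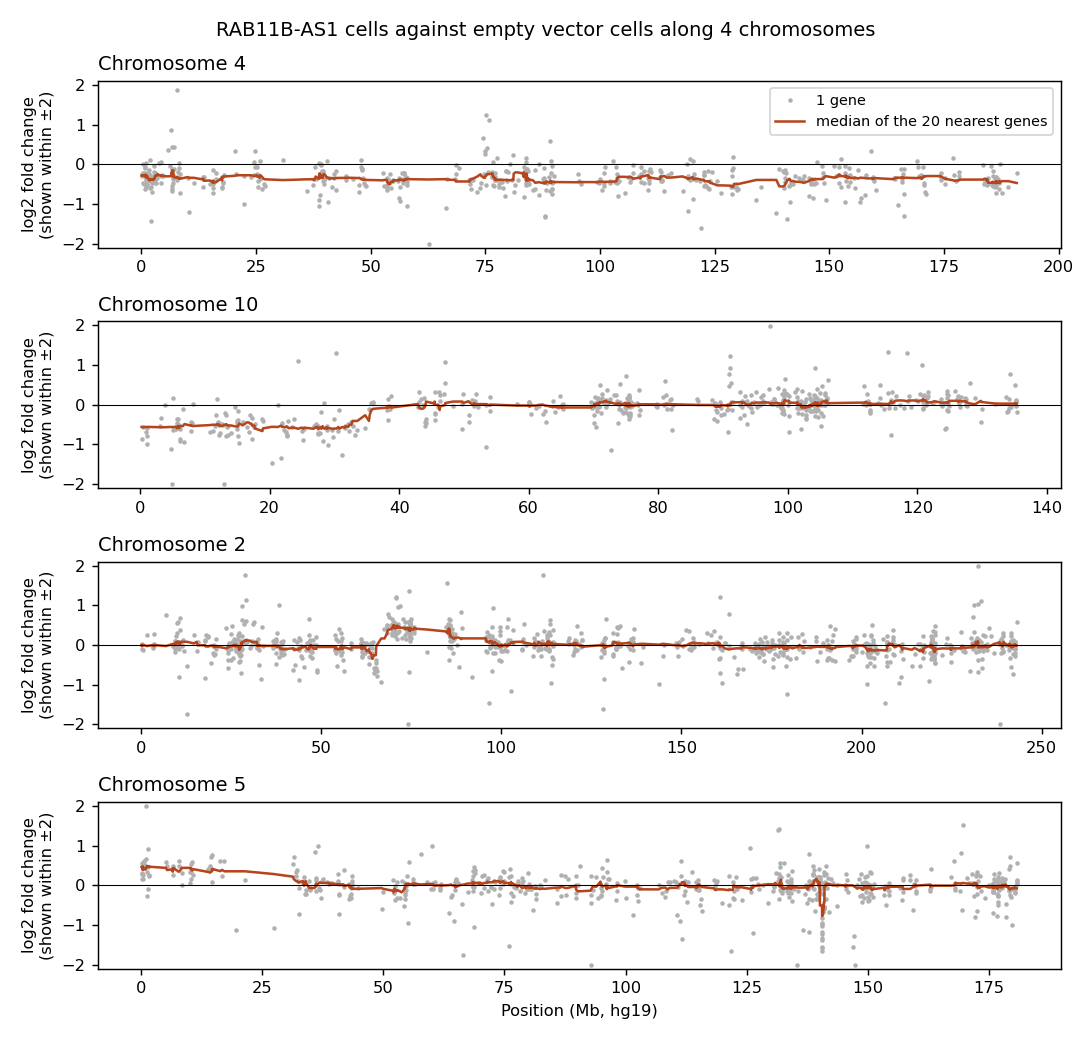
Log2 fold change of RAB11B-AS1 against empty vector cells, averaged over both oxygen levels (y axis, shown within 2 either way), along chromosomes 4, 10, 2 and 5 (x axis, position in Mb, hg19), with a grey point per tested gene and a red line for the median of the 20 nearest genes. The line runs below 0 along most of chromosome 4 and the start of chromosome 10, and above 0 along part of chromosome 2 and the start of chromosome 5.

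The response to low oxygen differed between the lines for 93 genes, among them 7 of 25 NF-kB and inflammatory genes. CSF2 stood at 6.62 ± 0.092 and 4.87 ± 0.98 TPM at 20% and 1% O2 in empty vector cells and at 7.72 ± 1.1 and 34.3 ± 4.1 TPM in RAB11B-AS1 cells (SD, n = 2). Its limma interaction on the log2 scale was 2.40 ± 0.20 (SE, adjusted p = 0.014). TRAF1 stood at 8.94, 9.43, 22.1 and 58.8 TPM in the same order (1.31 ± 0.11, adjusted p = 0.014). SOD2, the mitochondrial superoxide dismutase, stood at 93.1, 91.6, 119.8 and 187 TPM (0.66 ± 0.07, adjusted p = 0.014), and DUSP1 at 37.7, 139, 30.7 and 239.7 TPM (1.07 ± 0.13, adjusted p = 0.024). In the other direction, ALDOC rose from 2.46 to 12.5 TPM in empty vector cells and stood at 1.42 and 0.925 TPM in RAB11B-AS1 cells (-2.30 ± 0.22, adjusted p = 0.014). ID1, a repressor of differentiation factors, stood at 18.5, 42.7, 21.6 and 25.9 TPM (-0.91 ± 0.09, adjusted p = 0.014). RAB11B-AS1 (-0.22 ± 0.13, adjusted p = 0.49), RAB11B (-0.04 ± 0.13, adjusted p = 0.91), ANGPTL4 (0.40 ± 0.09, adjusted p = 0.14) and VEGFA (0.14 ± 0.09, adjusted p = 0.54) did not pass. Nor did CA9 (0.54 ± 0.15, adjusted p = 0.20), EPAS1 (0.19 ± 0.06, adjusted p = 0.22), HIF1A (-0.11 ± 0.08, adjusted p = 0.59) or ARNT (-0.07 ± 0.07, adjusted p = 0.69). In all 64 genes had a more positive response in RAB11B-AS1 cells and 29 a more negative one. The 93 calls became 0 without replicate 1 of empty vector cells at 1% O2 (1428 at an unadjusted p under 0.05) and 6 without its replicate 2. They became 1 or 4 without replicate 1 or 2 of RAB11B-AS1 cells at 20% O2, and 1 or 13 without replicate 1 or 2 of those at 1% O2. Without replicate 1 of empty vector cells at 20% O2 there were 1499, and without its replicate 2 there were 94. Fits without the filter gave 36 and without the variance trend 19, and voom on recovered reads gave 186.

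Of the 25 NF-kB and inflammatory genes, 7 had a more positive and 0 a more negative response in RAB11B-AS1 cells (19 and 1 adjusted over the list alone). The interaction list for NF-kB passed camera (adjusted p = 1.3e-14, but adjusted p = 0.11 with an estimated correlation). BIRC3 (0.77 ± 0.10) responded by 0.78 ± 0.07 in empty vector cells and by 1.55 ± 0.07 in RAB11B-AS1 cells. Immediate early genes had 5 more positive and 1 more negative response of 19 (10 and 1 adjusted over the list alone). Camera gave this list an adjusted p = 1.8e-06, but an adjusted p = 0.28 with an estimated correlation. Angiogenic factors had 2 each way of 29 (10 and 2 adjusted over the list alone), with STC1 (0.83) and the matrix-associated CYR61 (0.26) more positive and the growth factor PGF (-0.71) more negative. Camera called the angiogenic list towards the positive (adjusted p = 0.0026, but adjusted p = 0.19 with an estimated correlation). Cholesterol synthesis genes had 0 more positive and 1 more negative of 23 (0 and 12 adjusted over the list alone). Camera called the cholesterol list (adjusted p = 1.4e-11, but adjusted p = 0.11 with an estimated correlation), where FDFT1 passed (-0.33). Core hypoxia genes had 1 each way of 49 (4 and 8 adjusted over the list alone), and camera did not call their list (adjusted p = 0.23). HIF-2alpha-associated genes had 3 more positive and 0 more negative of 18 (5 and 1 adjusted over the list alone). Camera called the HIF-2alpha list towards the positive (adjusted p = 0.0026, but adjusted p = 0.19 with an estimated correlation). Camera called 14 of 35 lists, and with an estimated correlation 0 (7 at an unadjusted p under 0.05), while fry called 5.

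**Figure D3:**
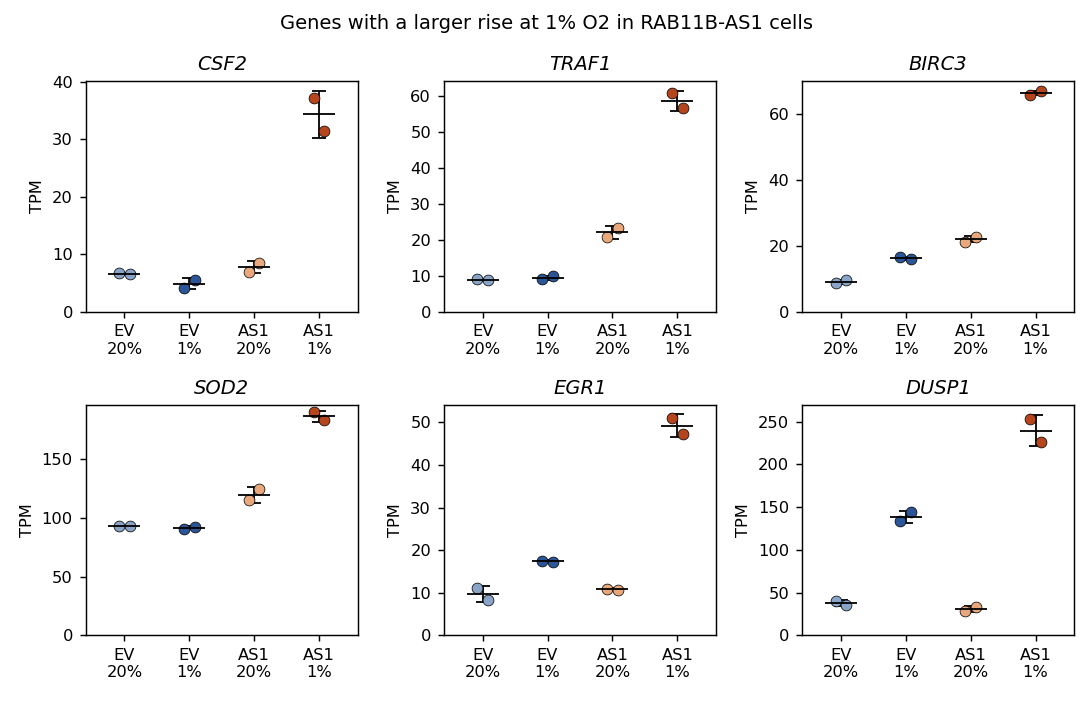
TPM (y axis) of CSF2, TRAF1, BIRC3, SOD2, EGR1 and DUSP1 in the 4 groups of 2 libraries (x axis), with a point per library, a horizontal bar at the mean and error bars of 1 SD. CSF2 means are 6.62 and 4.87 TPM in empty vector cells and 7.72 and 34.3 TPM in RAB11B-AS1 cells at 20% and 1% O2.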

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

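The tests that weigh explanations here were chosen after the interaction result was seen. Of the genes named by the fixed rule, the 32 reported here whose response to low oxygen differed between the lines, by the interaction test of the limma fit, are given with their interaction on the log2 scale (response in RAB11B-AS1 cells minus response in empty vector cells). More positive in RAB11B-AS1 cells were cytokine and NF-kB genes CSF2 (2.40), TRAF1 (1.31), BIRC3 (0.77) and SOD2 (0.66), and the immediate early genes EGR1 (1.29), DUSP1 (1.07), FOSL1 (0.72) and DUSP6 (0.40). So were the secreted or surface genes STC1 (0.83), IGFBP3 (0.46), CYR61 (0.26) and SLAMF9 (1.85), and the stress and metabolic genes MT1X (1.1), PHGDH (0.69), DNAJB9 (0.55) and TXNRD1 (0.36). More negative were the metabolic genes ALDOC (-2.30), IDH1 (-0.50), FDFT1 (-0.33), SCD (-0.28) and VLDLR (-0.50), together with C5orf46 (-1.36), ID1 (-0.91), PGF (-0.71), BAG3 (-0.38) and CTGF (-0.31). C5orf46 had 0 reads at 20% O2 and 1 at 1% O2 in RAB11B-AS1 cells, so its value reflects empty vector cells. Short RNA genes with few or no reads in some groups were MIR499B (3.70), MIR765 (1.86), MIR3615 (1.66), MIR148A (-1.46), MIR4691 (-1.89) and SNORD82 (-2.07).

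A pattern to follow up is that NF-kB genes responded more strongly to low oxygen in RAB11B-AS1 cells. Of 25, 7 passed and camera called the list (adjusted p = 1.3e-14, but adjusted p = 0.11 with an estimated correlation). Of the hypoxia lists, camera did not call the core list (adjusted p = 0.23). It called the list of HIF-2alpha-associated genes towards the positive (adjusted p = 0.0026, but adjusted p = 0.19 with an estimated correlation). The pattern is thus not particular to NF-kB genes, and differences between the lists were not tested. The long-transcript shift between the replicates of empty vector cells at 20% O2 is argued against as the whole cause. With the length trend of each library removed, 90 of the 93 genes were called again with the same sign. The refit without replicate 2 of that group met its bound. It cannot decide by itself, as it leaves 1 library there and which of the 2 is shifted is not known. Stronger oxygen deprivation in the RAB11B-AS1 cultures, acting in proportion on all hypoxia genes, is argued against only for these libraries. The slope of the fold changes in RAB11B-AS1 cells on those in empty vector cells was 0.973 ± 0.0376 (SE) over 49 core hypoxia genes. This SE is taken over genes, which are not independent replicates, and leaves out the spread between cultures. The slope covers the core list only, so stronger deprivation is not argued against for the HIF-2alpha list. What stays open is an effect of RAB11B-AS1, or of another lasting difference between the lines, on NF-kB genes at low oxygen, and these could not be separated, as the labels do not say whether each vector was carried by 1 pool of cells or by several clones. The pattern rests on few libraries: the calls fell to 0 without replicate 1 of empty vector cells at 1% O2 (1428 at an unadjusted p under 0.05), and a difference in culture state such as density may also contribute, which was not tested.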

How the results depend on the processing

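Tests with voom on recovered reads, with a length trend removed and on genes of at least 300 bp were chosen only after the results were seen. All other alternatives were planned. The counts of the 5 comparisons other than the interaction stayed within 1.5 times under both scalings, both filters, the smaller pseudocount, no variance trend and the 3 added tests. The excess of falls over rises in the main fit did depend on the scaling. With median-of-ratios scaling or voom, rises outnumbered falls in all 5, and with quantile scaling falls still did. For low oxygen in empty vector cells, median-of-ratios scaling gave 2326 rises and 2167 falls, against 2113 and 2541 in the main fit. Fits of only the groups compared gave 2413 and 6616 genes for low oxygen in empty vector and RAB11B-AS1 cells, and 2734 and 5649 for RAB11B-AS1 at 20% and 1% O2. Counts thus fell for the comparisons that use empty vector cells at 20% O2 and rose for the others. The libraries of that group differed most (chi-square per gene 13.9). The shared spread may therefore be too small for comparisons with that group and too large for those without it, which was not tested further. A 2-fold threshold, stricter by construction, left 239 and 326 genes for low oxygen in empty vector and RAB11B-AS1 cells, 393 and 401 for RAB11B-AS1 at 20% and 1% O2, 362 on average and 21 for the interaction. Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the other groups, gave 2552 to 5720 and 3161 to 6726 genes for low oxygen in the 2 lines, 2374 to 5630 and 3019 to 6244 for RAB11B-AS1 at 20% and 1% O2, and 5061 to 7271 on average. The counts fell most when a library of the compared groups other than empty vector cells at 20% O2 was removed.

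The interaction was the least stable count: 0 to 1499 genes over the leave-one-out fits, 36 without the filter, 19 without the variance trend, 186 with voom and 156 on genes of at least 300 bp, against 93. For these, the cause was not tested. Replicate 1 of empty vector cells at 1% O2 gave 0 when removed (1428 at an unadjusted p under 0.05), replicate 1 of empty vector cells at 20% O2 gave 1499. Camera with an estimated correlation called 8 and 9 lists for low oxygen in the 2 lines, and 0 for RAB11B-AS1 at 20% O2, at 1% O2, on average and for the interaction (3, 7, 5 and 7 at an unadjusted p under 0.05). Fry called 25, 28, 29 and 5 there. The Pearson correlation between the hypoxia comparisons was 0.544 with a pseudocount of 0.1 and 0.789 with the filter at 5 TPM, and between the RAB11B-AS1 comparisons 0.671 and 0.800, and the cause was not tested. Across the 203 fold changes of named genes, each a gene in 1 comparison, no direction of a call turned. Of the 1624 leave-one-out values of these, 232 lost their call and 12 gained one. Calls lost were 23 without the filter, 24 without the trend and 9 with a pseudocount of 0.1. DESeq2, planned only for counts, was not run, and depth limits genes with few reads, above all short RNA genes.

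The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated between -0.078 and 0.074. With the replicate number as a block, the interaction gave 37 genes, of which 33 were also called without it, and 19 of the fold changes of named genes lost their call.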

Other observations

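The tests of the long-transcript shift, of genes on in only 1 line, of the share of genes in shifted stretches and of microRNA genes were chosen after the result was seen, and those of the shift and of microRNA genes were rewritten after their values were known. The others on gene differences between the lines and on small nucleolar RNA genes were written before. Small nucleolar RNA (snoRNA) genes, a list chosen after seeing the data, were lower at 1% O2. Of 207 tested, 66 fell and 2 rose in empty vector cells, with a median log2 fold change of -0.59 (camera, unadjusted p = 4.2e-07, and p = 0.0041 with an estimated correlation). Likewise 72 fell and 4 rose in RAB11B-AS1 cells, with a median of -0.69 (p = 2.8e-06, and p = 0.0054 with an estimated correlation). Summed reads of these genes went from 148 ± 11.9 to 92.5 ± 6.67 per 1000000 reads in empty vector cells and from 163 ± 3.91 to 96.1 ± 0.625 per 1000000 reads in RAB11B-AS1 cells (SD, n = 2).

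For the snoRNA pattern, few reads per gene (a median of 6.5 per library) are argued against as the cause, because the summed reads per 1000000 at 1% O2 were 0.626 of those at 20% O2 in empty vector cells and 0.589 in RAB11B-AS1 cells, without overlap. Loss of reads from all genes listed as short is argued against too. The summed reads of the 282 tested microRNA genes at 1% O2 were 1.01 and 1.05 of those at 20% O2 in the 2 lines. Of these genes, 27 rose and 16 fell in empty vector cells, and 24 rose and 22 fell in RAB11B-AS1 cells. The first bound, a median above 0 in both lines, was missed (-0.05 and 0.0). Whether microRNA gene reads come from short RNA or from longer transcripts was not examined, so a loss of short RNA molecules stays open. Lower expression of host genes stays open: over 144 snoRNA genes in 84 hosts, the median difference, snoRNA minus host, was -0.335 ± 0.068 (SE) and -0.540 ± 0.071, and the first missed, by a small margin, the bound of 2 standard errors below -0.2, although the hosts' own medians were -0.16 and -0.09 and 106 and 101 of the 144 lay below their host. Poly(A)-selected libraries hold snoRNA reads only in part, so a change in processing, in host transcription or in carry-over of short RNA could give the pattern. No biological explanation was tested beyond the hosts.

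Splits of the libraries do not exclude chance for the difference between the lines at both oxygen levels. With oxygen as a term, 34 splits of the 8 libraries into 4 and 4 could be fitted. Only 1, the real one, gave as many genes (5908, and 0 in the highest other). At an unadjusted p under 0.05 these were 6915 and at most 1534. However, the splits that part each oxygen level evenly number only 18, too few for a share under 0.05. The labels also do not say whether the libraries of a group are separate cultures. The long-transcript shift is argued against as the whole cause. With the length trend of each library removed, 6198 of the 6347 genes were called again with the same sign. Without replicate 2 of empty vector cells at 20% O2, 6008 of the 6347 were called again with the same sign. That refit cannot decide by itself, as it leaves 1 library there and which of the 2 is shifted is not known. Regional copy-number differences between the lines may account for genes in shifted stretches with like medians at both oxygen levels. The second stretch of chromosome 5 had unlike medians (-0.36 at 20% O2 and -0.77 at 1% O2). Genes with shifted neighbours, in runs of any length, were 9.09% of the tested genes. This was 7.97 times the higher of the shares in the hypoxia comparisons. Of the genes that passed on average, 14.6% had neighbours shifted their way. The share was 15.2% at 1% O2, and 20.4% at 20% O2, just over the bound of 20% set for the average. Broad shifts of this size are thus argued against as the whole cause. Shorter or smaller copy-number differences escape this measure and stay open. Lasting differences between the lines other than the RNA stay open: 2 genes, KRBOX1 and C5orf46, were under 0.5 TPM in all libraries of RAB11B-AS1 cells and at 5 TPM or more in all of empty vector cells. That number met a bound of fewer than 5, set after related values were seen, but the bound was set wrongly: a difference between lines need not switch genes off, and the labels do not say whether each vector was carried by 1 pool or several clones, so the verdict was changed to open after the value was known.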
